A study of Mus musculus with 23 samples.

How the data were processed

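Mouse retina, brain and cortex were measured as single-cell RNA-seq (4 retinal and 2 cortical libraries), Ribotag RNA-seq of Müller glia (4 libraries), whole-retina RNA-seq (4 libraries) and whole-brain RNA-seq (9 libraries). The authors deposited single-cell counts as UMI counts per gene and barcode, with an annotation of every barcode to a cell class or to multiplets, and the bulk tables as TPM per gene. The submitters' processing notes named Cell Ranger 2.1.0 and kallisto (version not given in the sources used here) and the build mm10. Per the labels, single-cell libraries used polyadenylated RNA and bulk libraries total RNA. The bulk files held TPM in place of the counts planned for, so limma on log2(TPM + 1) was used in place of a count model. The authors' annotation was used in place of new clustering, and the multiplets it named were left out in place of a doublet caller.

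Groups came from source names and titles. The genotype tag of both NdpKO whole-retina libraries read WT and the treatment tags of the cortex libraries were reversed, so Ndp levels and the agreement in sign with whole brain were checked and are printed with the results. Gene coordinates came from GENCODE vM21 on GRCm38 (mm10), to which 49721 of the bulk gene names were matched. The single-cell matrices had 27998 entries with 27933 symbols.

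For bulk data, genes with a mean of at least 1 TPM in a group were kept, and a model with all groups of the tissue was fitted by limma 3.58.1 with a trend in R 4.3.3. Calls had a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The retinal model held genotype, RNA source and their interaction. Because TPM keeps no depth, the precision of a bulk library was not computed, and the median SE of a log2 change, 0.148 in brain and 0.379 in retina, served as its measure. The median of all genes was subtracted where it passed 0.1 log2. Within a list, p-values were also adjusted over the list alone.

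For retinal single cells, barcodes with at least 500 UMIs and at most 20 percent mitochondrial UMIs were kept. UMIs were summed per library and class, in classes with at least 20 cells in every library, and tested by edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) with 2 libraries per genotype. Endothelial, perivascular and horizontal cells had fewer cells and were tested with a minimum of 10, chosen after the data were seen. Retinal CPM were computed over the tested genes of a class with TMM scaling. Where a gene had 0 UMIs in a genotype, the fold was computed against a floor of 3 counts. With 1 to 3 UMIs the ratio and its exact 95 percent counting interval were given. Cortex classes were compared as CPM over all UMIs with exact intervals, without a test, and lists against 10000 random lists drawn within 50 ranks in level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for loading, cortex values and figures.

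Gene lists were written before the data were examined. They were tested by camera with a preset correlation of 0.01 and again with a correlation estimated from the data. Of 416 list tests in 13 comparisons 184 were called with the preset and 0 with the estimated correlation. With so few libraries the estimated setting may have had little power. Named genes followed a rule fixed in advance: per bulk comparison the 6 largest rises and falls among called genes of at least 10 TPM without overlap between groups, per single-cell class 4 and 4 at 50 CPM, per cortex class 5 and 5 at 100 CPM and 30 UMIs, and 3 members of each leading list. Overlaps of calls were tested by Fisher's exact test.

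Settings varied by prior choice were DESeq2 1.42.0 size factors and Wald test, no filter on low values, a pseudocount of 0.1, at least 1000 UMIs per cell, thinning to 500 UMIs, multiplets kept in the total, a replicate block, only the groups compared, and every library left out in turn. Added after the data were seen were rescaling to the protein-coding total, median-of-ratios scaling, all annotated barcodes, rods left out of the total, bipolar cells split into rod and cone bipolar cells, and the minimum of 10 cells.

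The tests were tried on simulated data with known changes. Genes were drawn independently, with no shift of a whole library and no correlation between genes. The shares of false calls may therefore not carry over to the real libraries. With the spread of brain at 7 d (20397 genes) 12.0 percent of changes of 0.5 log2 and 83.0 percent of changes of 1 log2 were called, with 8.65 percent false calls. With that of Müller Ribotag RNA (25956 genes) 2 percent were called at 1 log2 and 53.0 percent at 2 log2, with 3.51 percent false. For single Müller glia (6346 genes) 25.0 and 88.5 percent were called at 1 and 2 log2, with 0.917 percent false, and for bipolar cells (10094 genes) 71.7 and 98.9 percent, with 7.3 percent false. DESeq2 called 8.7 and 65.6 percent in Müller glia and 43.4 and 90.5 percent in bipolar cells. Retinal microglia and astrocytes (8 cells in the smallest library) and cortical GABAergic neurons (18 cells) were not tested. Results for a few genes are not reported here.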

Results

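The series compared retinas of mice lacking Norrin, the secreted ligand encoded by Ndp that drives retinal vessel growth through Fzd4, Lrp5 and Tspan12, with retinas of wild-type mice, and compared brains of mice kept at 7.5 percent oxygen with brains of mice kept in normoxia. All mice were C57BL/6J and 2 months old. Dissociated retina was profiled by single-cell RNA-seq in 2 NdpKO and 2 WT libraries, and polysome-bound RNA of Müller glia (Ribotag pulldown) by bulk RNA-seq in 2 NdpKO and 2 WT libraries. Whole retina was profiled by bulk RNA-seq in 2 NdpKO and 2 WT libraries, whole brain in 3 libraries each of normoxia, 48 h and 7 d of hypoxia, and dissociated cortex by single-cell RNA-seq in 1 library of 7 d hypoxia and 1 of normoxia. The labels gave male mice for the single-cell and brain libraries and mixed sex for the Ribotag and whole-retina libraries, which came from pooled retinas. The labels did not state that libraries of a group came from separate litters or pools. The p-values of single genes therefore measured the spread between these libraries, which may be technical. Camera p-values with the preset correlation compared list members with other genes, and Fisher p-values counted genes. Neither of these measured the spread between libraries.

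The bulk tables held TPM, a unit that keeps no sequencing depth, so depth per bulk library was not used here. In each bulk library 17514 to 24747 genes reached 1 TPM. The retinal single-cell libraries held 9939 and 7640 annotated barcodes with 18839359 and 7787182 UMIs (NdpKO) and 7551 and 7695 barcodes with 6579705 and 7405416 UMIs (WT). After multiplets, barcodes under 500 UMIs and barcodes above 20 percent mitochondrial UMIs were left out, 7535 and 3571 NdpKO cells (median 1150 and 1305 UMIs) and 3625 and 3772 WT cells (median 1161 and 1299.5 UMIs) remained. The cortex libraries held 4007 barcodes and 14960179 UMIs (hypoxia) and 3918 barcodes and 13348660 UMIs (normoxia), with 3883 and 3837 cells kept at a median of 2660 and 2632 UMIs.

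Ndp (X:16885521-16911774, GENCODE vM21 on GRCm38) was examined in every library. In Müller Ribotag RNA it stood at 22.1 and 19.4 TPM in WT and at 2.82 and 2.94 TPM in NdpKO, a change of -2.72 log2 relative to the median of all genes (SE 0.31, limma adjusted p = 0.0133, n = 2 and 2). In whole retina it stood at 5.91 and 5.36 TPM in WT and at 2.45 and 3.92 TPM in NdpKO (log2 change -0.69, SE 0.31, limma adjusted p = 0.183), where the libraries named NdpKO carried a WT genotype tag. The change in Ribotag RNA was the larger by -2.16 log2 (SE 0.44, limma adjusted p = 0.0357). The retinal single-cell libraries held 12 and 2 Ndp UMIs in NdpKO and 49 and 66 in WT. In horizontal cells Ndp fell from 31 UMIs in WT to 2 in NdpKO, a ratio of 0.0173 (95 percent counting interval 0.002 to 0.0679, edgeR adjusted p = 7.19e-05). In brain Ndp stood at 2.995, 2.77 and 2.95 TPM in normoxia, at 3.34, 3.11 and 3.51 TPM at 48 h (limma adjusted p = 0.463) and at 2.59, 3.48 and 3.06 TPM at 7 d (limma adjusted p = 0.846, n = 3 per group). The cortex libraries held 257 Ndp UMIs in hypoxia and 195 in normoxia (17.8 and 15.1 CPM).

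**Figure D1:**
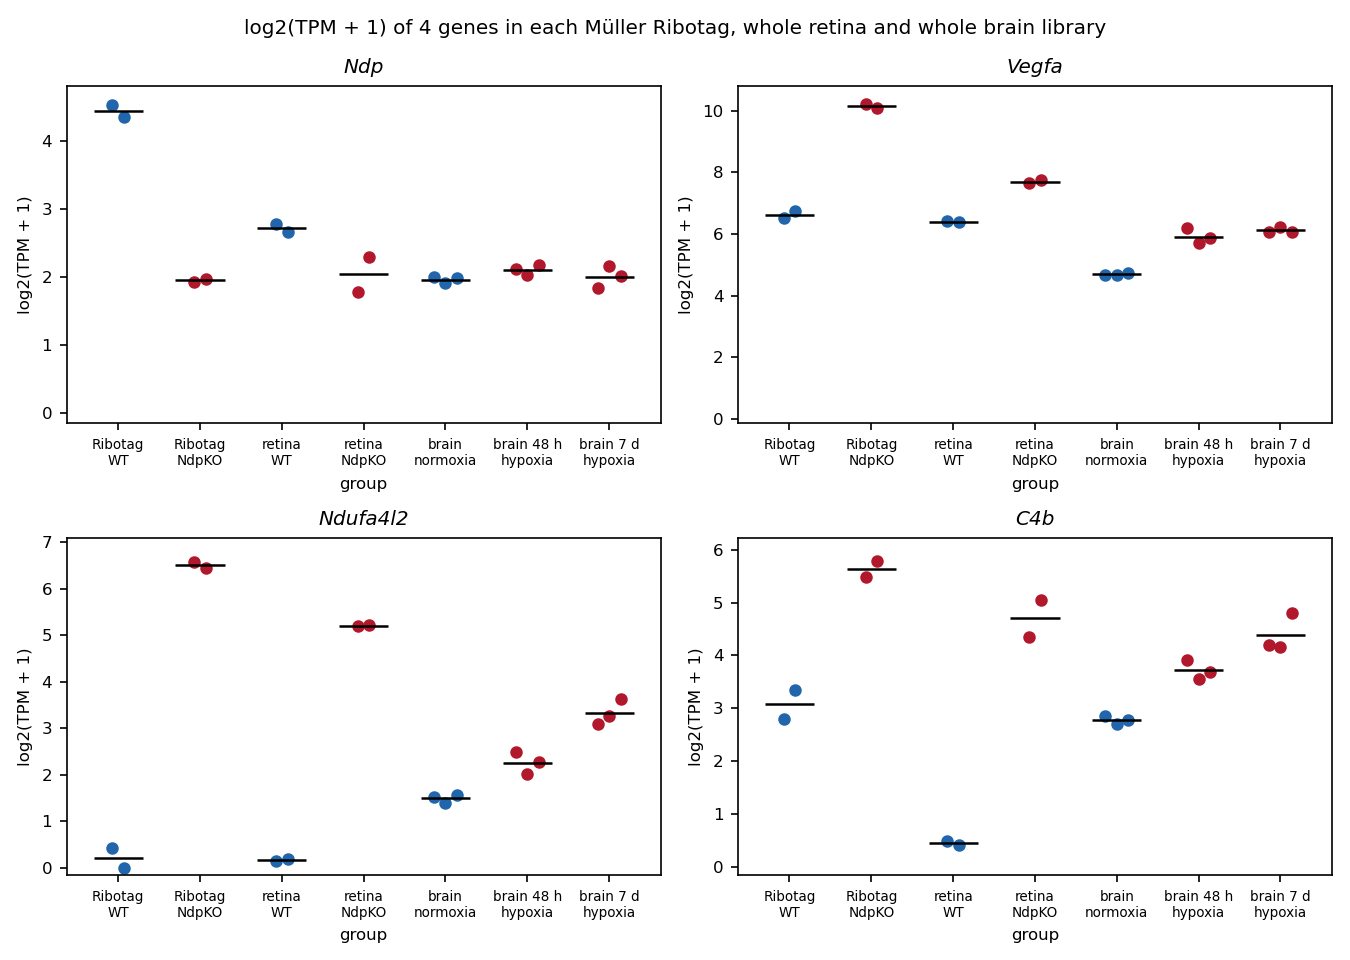
Levels of Ndp, Vegfa, Ndufa4l2 and C4b in bulk RNA-seq as log2(TPM + 1), with a point per library and a bar at the mean of each of 7 groups (n = 2 for retinal groups, n = 3 for brain groups). Vegfa rose from a mean of 98.5 to 1139 TPM in Müller Ribotag RNA and from 24.8 to 68.5 TPM in brain after 7 d of hypoxia.

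Müller Ribotag RNA of NdpKO retina carried more transcript of some hypoxia-inducible genes. Vegfa (17:46016993-46032369), the main angiogenic growth factor, rose from 98.5 ± 11.1 to 1139 ± 67.9 TPM (mean ± SD, 3.29 log2, SE 0.17, limma adjusted p = 0.000107, n = 2 and 2). Ndufa4l2 (10:127514967-127517154), a mitochondrial protein induced by HIF, rose from 0.178 ± 0.252 to 90.0 ± 4.89 TPM (6.05 log2, SE 0.29, adjusted p = 8.53e-05). Apln, the ligand of the apelin receptor and a tip cell gene, rose from 6.10 to 69.1 TPM (3.06 log2, SE 0.35, adjusted p = 0.00843). Slco1c1 (6:141524368-141570177), a transporter of thyroxine, fell from 22.5 ± 1.57 to 3.80 ± 0.219 TPM (-2.53 log2, SE 0.34, adjusted p = 0.0197). Changes in this comparison, in both brain comparisons with normoxia and in the difference between the genotype effects are given relative to the median of all genes, which stood at 0.24, 0.20 (48 h), 0.17 (7 d) and 0.36 log2 in turn. The tests used the unshifted values, and all called rises and falls also lay above and below that median. The log2(TPM + 1) scale understates changes of genes near 0.

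Of 29 measured hypoxia-inducible genes, 7 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone (median 0.19 log2, camera adjusted p = 0.00226, adjusted p = 0.262 with an estimated correlation). Adm, the vasodilator adrenomedullin, rose from 0.256 to 6.38 TPM (2.29 log2, adjusted p = 0.0198). Of 18 tip cell genes 3 rose, among them Plod2, a collagen lysine hydroxylase, which reached 175 TPM (0.98 log2, adjusted p = 0.0434). Among 18 glycolytic genes 1 rose, Pfkp (1.22 log2, adjusted p = 0.0361), and 1 fell, Pfkm (-1.07 log2, adjusted p = 0.0426), with 5 rises and 2 falls over the list alone and no call by camera (adjusted p = 0.750). Of 20 gliosis genes 6 rose and 0 fell (12 and 0 over the list alone, median 0.55 log2, camera adjusted p = 7.29e-05, adjusted p = 0.405 with an estimated correlation). These included the complement component C4b (from 7.59 to 48.7 TPM, 2.31 log2, adjusted p = 0.0145), the protease inhibitor Serpina3n (from 26.4 to 119 TPM, 1.87 log2, adjusted p = 0.0171) and Edn2, endothelin 2 (from 3.52 to 22.1 TPM, 2.11 log2, adjusted p = 0.011). Interferon-response genes gave 2 rises among 12, Xaf1 (2.54 log2, adjusted p = 0.0304) and Ifitm3 (0.98 log2, adjusted p = 0.0402), with 5 over the list alone (camera adjusted p = 0.00915, adjusted p = 0.819 with an estimated correlation). Hmox1, which breaks down heme, rose from 4.67 to 25.8 TPM (2.01 log2, adjusted p = 0.0133). None of 23 Müller glia markers passed.

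Some sterol synthesis genes were lower in the same libraries. Of 18 measured, 4 fell and 0 rose (6 fell over the list alone, median -0.89 log2, camera adjusted p = 1.36e-08, adjusted p = 0.262 with an estimated correlation). Among them were the isomerase Idi1 (from 51.1 to 15.1 TPM, -1.89 log2, adjusted p = 0.0224) and Hmgcs1 (-1.53 log2, adjusted p = 0.036). Bipolar cell markers fell in 10 of 18 genes and in 15 over the list alone (median -1.80 log2, camera adjusted p = 3.62e-15, adjusted p = 0.405 with an estimated correlation). Scgn, a calcium-binding protein, stood at 172 and 29.4 TPM (-2.72 log2, SE 0.25, adjusted p = 0.00654) and Gng13, a G protein subunit, at 660.0 ± 122 and 124 ± 35.8 TPM (-2.66 log2, adjusted p = 0.0285) in WT and NdpKO. Sebox, a homeobox gene, fell from 105.8 ± 66.7 to 8.39 ± 6.76 TPM (-3.80 log2, SE 0.65, adjusted p = 0.0308). Nuclear genes for oxidative phosphorylation fell in 8 of 70 cases and in 22 over the list alone (median -0.82 log2, camera adjusted p = 5.94e-18, adjusted p = 0.454 with an estimated correlation). Atp5g1 stood at -2.28 log2 (adjusted p = 0.0154) and Ndufa13 at -1.99 log2 (adjusted p = 0.0171). Ribosomal protein genes fell in 5 of 54 cases (19 over the list alone, adjusted p = 0.557 with an estimated correlation), among them Rplp1 (-3.19 log2, adjusted p = 0.0195) and Rps18 (-2.44 log2, adjusted p = 0.0271). Pdc, a phosducin of photoreceptors, fell from 625 to 206 TPM (-1.83 log2, adjusted p = 0.0266).

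Across all genes 1231 of 25956 passed in Müller Ribotag RNA, with 809 rises and 422 falls. At least 1 TPM was reached by 21582 and 24747 genes in the NdpKO Ribotag libraries and by 18336 and 19354 in WT. The number of genes detected thus went with genotype, and its part in the excess of rises was not tested. The largest changes by rule were mostly genes without an assigned function or pseudogenes. AY036118, listed at 0 in WT, reached 3104 ± 1573 TPM (11.26 log2, SE 0.38, adjusted p = 1.62e-05). AC131720.2, AC156576.2 and AC159747.1 rose by 8.86, 7.41 and 6.89 log2 (adjusted p = 0.00621, 0.00703 and 0.0117). Pla2g10os rose by 5.97 log2 (adjusted p = 0.000519). Rpl19-ps11, Rpl9-ps4 and Rps3a2 changed by -7.02, -6.74 and -6.53 log2 (adjusted p = 3.94e-05, 0.000434 and 0.0256), and AC167420.1 and AC139941.1 by -4.14 and -3.57 log2. Reads of such pseudogenes cannot be separated with certainty from their parent genes. Sex-linked transcripts also differed. Xist stood at 9.14 and 26.2 TPM in WT and at 65.8 and 33.8 TPM in NdpKO. Of 5 sex-linked genes 3 rose, with Eif2s3y at 1.88 log2 (adjusted p = 0.0171), Kdm5d at 1.24 log2 (adjusted p = 0.0246) and Uty at 1.07 log2 (adjusted p = 0.0252). Without the second WT library 7 genes passed, and without NdpKO replicate 1 there were 5001.

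In whole retina of NdpKO mice some glial, interferon and hypoxia genes were higher. Ndufa4l2 rose from 0.122 ± 0.0283 to 35.7 ± 0.392 TPM (5.03 log2, SE 0.29, limma adjusted p = 0.00013, n = 2 and 2). Vegfa rose from 83.6 ± 1.79 to 207 ± 8.26 TPM (1.30 log2, SE 0.17, adjusted p = 0.00307) and Apln from 1.36 to 32.7 TPM (3.89 log2, adjusted p = 0.000873). Gfap (11:102887336-102900912), the intermediate filament of reactive glia, rose from 2.00 ± 0.617 to 36.7 ± 0.0583 TPM (3.67 log2, SE 0.30, adjusted p = 0.00052). Edn2 (4:120161206-120167360), made by stressed photoreceptors, rose from 0.641 to 35.0 TPM (4.46 log2, SE 0.28, adjusted p = 0.000173).

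Of 20 gliosis genes 11 rose in whole retina and 0 fell (17 over the list alone, median 1.51 log2, camera adjusted p = 3.44e-10, adjusted p = 0.230 with an estimated correlation). Of 29 hypoxia-inducible genes 10 rose and 0 fell (13 over the list alone, camera adjusted p = 3.4e-06, adjusted p = 0.179 with an estimated correlation). C4b rose from 0.364 to 25.7 TPM (4.25 log2, adjusted p = 0.000473). Interferon-response genes rose in 10 of 12 cases (11 over the list alone, median 2.60 log2, camera adjusted p = 8.87e-09, adjusted p = 0.308 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like protein, stood at 3.47 and 73.5 TPM (4.06 log2, adjusted p = 0.000944) and Ifi27 at 2.82 log2 (adjusted p = 0.00124). All 3 metallothioneins, which bind zinc and copper, rose (camera adjusted p = 0.00108, adjusted p = 0.288 with an estimated correlation). Mt3 stood at 4.12 log2 (adjusted p = 0.00135) and Mt2 at 3.40 log2 (adjusted p = 0.00339). Immediate early genes rose in 7 of 15 cases (8 over the list alone, camera adjusted p = 0.000195, adjusted p = 0.379 with an estimated correlation). Junb stood at 2.51 log2 (adjusted p = 0.00623). Glycolytic genes rose in 6 of 18 cases (7 over the list alone, camera adjusted p = 0.00222, adjusted p = 0.416 with an estimated correlation). Hk1, a hexokinase, stood at 2.11 log2 (adjusted p = 0.00124), Pfkl at 1.78 log2 (adjusted p = 0.00163) and the glucose transporter Slc2a1 at 1.16 log2 (adjusted p = 0.00536).

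Cell type markers moved as well. Of 23 Müller glia markers 12 rose and 1 fell in whole retina (13 and 2 over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.399 with an estimated correlation). The lipid carrier Apoe rose from 147 to 2309 TPM (4.02 log2, adjusted p = 0.000238) and Glul, glutamine synthetase, from 623 to 3120 TPM (2.33 log2, adjusted p = 0.00115). Microglia markers rose in 6 of 16 cases (camera adjusted p = 0.00325, adjusted p = 0.399 with an estimated correlation). The complement gene C1qa stood at 2.88 log2 (adjusted p = 0.00515) and the receptor Trem2 at 1.77 log2 (adjusted p = 0.015). Basement membrane genes rose in 4 of 13 cases (camera adjusted p = 0.000461, adjusted p = 0.230 with an estimated correlation). The collagen gene Col4a1 stood at 3.33 log2 (adjusted p = 0.000511) and Col4a2 at 1.80 log2 (adjusted p = 0.0102). Of 13 Norrin and beta-catenin genes 3 rose and 1 fell, the rises including the Wnt targets Nkd1 and Axin2 by 1.23 and 1.18 log2 (adjusted p = 0.0205 and 0.033) and the fall being Slco1c1, from 4.32 to 1.196 TPM (-1.23 log2, adjusted p = 0.0445). Amino acid response genes rose in 4 of 20 cases (camera adjusted p = 0.00185, adjusted p = 0.288 with an estimated correlation), with Slc3a2, a subunit of amino acid transporters, at 79.6 and 879.7 TPM (3.45 log2, adjusted p = 6.15e-05). Phgdh, which starts serine synthesis, rose by 1.80 log2 (adjusted p = 0.0107), and the selenoenzymes Gpx4 and Txnrd1 rose by 2.41 and 1.90 log2 (adjusted p = 0.00176 and 0.00446).

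In whole retina 3946 of 25956 genes passed, 2201 with a rise and 1745 with a fall, and scaling by median of ratios gave 46.1 percent rises in place of 55.8 percent. The largest changes by rule were again mostly pseudogenes and unassigned genes. Pgk1-rs7 (7.36 log2, listed at 0 in WT), Cbx3-ps6 (7.00), Rpl38-ps2 (6.78), Rps13-ps1 (6.70), Ftl2-ps (6.56) and Snurf (6.29) rose, in log2 units. AA465934 (-7.97, from 2528 ± 278 to 9.48 ± 4.20 TPM), Rps13-ps2 (-6.32), Hmga1b (-5.88) and AC154368.2 (-5.73) fell. Library makeup differed with genotype. Mitochondrial ribosomal RNA made up 20.95 and 19.0 percent of TPM in WT and 5.71 and 4.89 percent in NdpKO. The small transcript CT010467.1 made up 3.35 and 0.72 percent in WT and 12.3 and 9.42 percent in NdpKO. Xist stood at 7.51 and 18.9 TPM in WT and at 0.101 and 0.0736 TPM in NdpKO, although the labels gave mixed sex for both. Without the second NdpKO library 656 genes passed.

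The genotype effect was then compared between Ribotag RNA and whole retina, and 3325 genes differed, 1794 with a higher value in Ribotag RNA and 1531 with a lower one (63.9 percent higher by median of ratios, 54.0 percent by TPM). Vegfa rose more in Ribotag RNA, by 1.87 log2 (SE 0.24, limma adjusted p = 0.00405), as did Hmox1 (1.80 log2, adjusted p = 0.0161). Gfap (-3.00 log2, adjusted p = 0.012), Edn2 (-2.47 log2, adjusted p = 0.0168), and Col4a1 (-4.03 log2, adjusted p = 0.00381) had a lower effect in Ribotag RNA, as had Apoe (-4.07 log2, adjusted p = 0.00363), Slc3a2 (-3.80 log2, adjusted p = 0.000681) and Phgdh (-2.79 log2, adjusted p = 0.0185). The lactate exporter Slc16a3 (-2.54 log2, adjusted p = 0.0205) and Hk1 (-2.32 log2, adjusted p = 0.0109) did so as well. The Müller glia marker Rlbp1, a retinaldehyde-binding protein, differed by -2.59 log2 (adjusted p = 0.00742). It was 1 of 9 among 23 markers of that cell type with a lower effect in Ribotag RNA, while 1 had a higher effect (all lists at adjusted p of 0.425 or more with an estimated correlation). Calls shared by Ribotag RNA and whole retina numbered 79 rises (68.6 expected, Fisher p = 0.104) and 74 falls (28.37 expected, p = 2.58e-14), with 120 genes in opposite directions (90.17 expected). Both comparisons came from the same fit, with the same estimate of spread per gene. Genes of small spread can thus be called in both, which the expected counts and Fisher p-values do not allow for. Without the second whole-retina NdpKO library the difference was called for 184 genes.

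Wild-type Ribotag RNA carried more Müller glia transcript than whole retina. All 23 markers were higher (median 3.30 log2, camera adjusted p = 3.92e-28, adjusted p = 0.108 with an estimated correlation). Rlbp1 stood at 145 and 2369 TPM (4.01 log2, limma adjusted p = 0.000128) in retina and Ribotag RNA. Higher too were Ndp (1.71 log2, adjusted p = 0.00786), the serine aminotransferase Psat1 (34.4 and 363 TPM, 3.34 log2, adjusted p = 0.000139) and Slco1c1 (2.19 log2). Lower were 14 of 17 rod markers, such as the transducin Gnat1 (-2.63 log2, adjusted p = 0.00102), and 8 of 14 cone markers, such as the opsin Opn1mw (-2.99 log2, adjusted p = 0.000135). So were 11 of 15 amacrine markers, such as Gad1, which makes GABA (-3.25 log2, adjusted p = 0.000169), and 8 of 13 ganglion cell markers, such as Pou4f1 (-3.31 log2, adjusted p = 0.000512). Bipolar markers went the other way, with 6 of 18 higher and 1 lower (median 0.74 log2, camera adjusted p = 0.0259, adjusted p = 0.620 with an estimated correlation). Among them were Gng13 (2.65 log2, adjusted p = 0.00479) and Pcp2 (2.37 log2, adjusted p = 0.00707). The largest differences by rule were for Rpl10-ps1, Sptb, Crip1, Spc25, Plac9b and S100a6 (6.29, 5.64, 5.33, 4.99, 4.95 and 4.91 log2) and for AC131720.2, AC153662.1, AC156576.2 and St8sia3os (-7.44, -5.73, -4.94 and -3.91 log2). Of 4075 genes called, 78.6 percent were higher in Ribotag RNA, against 58.7 percent after rescaling to protein-coding genes and 51.0 percent by median of ratios.

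In single Müller glia of NdpKO retina some hypoxia-inducible and glycolytic genes were higher and some sterol genes lower. Ndufa4l2 rose from 10.97 ± 2.53 to 1604 ± 363 CPM (7.17 log2, SE 0.38, edgeR adjusted p = 3.61e-08, n = 2 and 2). Vegfa rose from 130.0 ± 8.64 to 746 ± 42.2 CPM (2.52 log2, SE 0.23, adjusted p = 2.7e-05) and Ldha, lactate dehydrogenase A, from 425 to 1130 CPM (1.41 log2, SE 0.20, adjusted p = 0.00124). Adm had 0 UMIs in WT and 697 in NdpKO, at least 39.8-fold higher (adjusted p = 0.000123), and the ratio of Apln was 33.5 (95 percent counting interval 9.22 to 278, adjusted p = 0.000123). Slco1c1 fell from 74.1 ± 33.5 to 4.10 ± 1.49 CPM (-3.98 log2, SE 0.53, adjusted p = 0.000644). Counting intervals here and below cover counting error only. CPM of retinal classes were taken over the UMIs of the genes tested in the class, after TMM scaling, and those of cortex classes over all UMIs, so levels do not compare between them.

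Glycolytic genes rose in 8 of 18 cases in Müller glia (13 over the list alone, median 1.00 log2, camera adjusted p = 1.36e-13, adjusted p = 0.322 with an estimated correlation). Pfkp stood at 1.80 log2 (adjusted p = 0.000502) and Gpi1 at 1.25 log2 (adjusted p = 0.00704). Hypoxia-inducible genes rose in 7 of 19 cases (7 over the list alone, camera adjusted p = 3.26e-11, adjusted p = 0.322 with an estimated correlation). Gliosis genes rose in 4 of 13 cases and fell in 1 (9 and 1 over the list alone, camera adjusted p = 4.39e-05, adjusted p = 0.322 with an estimated correlation). C4b stood at 10.97 and 99.0 CPM (3.15 log2, SE 0.44, adjusted p = 0.000938) and S100a6 at 1.68 log2 (adjusted p = 0.000938), while Gfap stood at 1.37 log2 (adjusted p = 0.105). Interferon-response genes rose in 4 of 11 cases (camera adjusted p = 3.09e-07, adjusted p = 0.322 with an estimated correlation), among them Isg15 (2.69 log2, adjusted p = 0.00325) and Ifit1 (ratio 11.1, counting interval 3.74 to 54.2, adjusted p = 0.0189). Sterol synthesis genes fell in 3 of 13 cases (10 over the list alone, median -1.05 log2, camera adjusted p = 1.06e-09, adjusted p = 0.322 with an estimated correlation). Insig1 stood at -2.19 log2 (adjusted p = 0.00101) and Msmo1 at -1.42 log2 (adjusted p = 0.0133). Falls by rule included the phosphodiesterase Pde10a (-2.97 log2, adjusted p = 0.000123), the cytokine-signalling inhibitor Socs3 (from 451 to 80.9 CPM, -2.55 log2, adjusted p = 4.54e-05) and the deiodinase Dio2, which activates thyroid hormone (from 196 to 42.9 CPM, -2.25 log2, adjusted p = 0.000227). The ratio of Fn1, fibronectin, was 33.3 (5.9 to 1320, adjusted p = 0.00647). In all, 96 of 6613 genes passed, 62 with a rise and 34 with a fall.

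Ribotag and single-cell Müller calls overlapped in 21 rises (0.6108 expected, Fisher p = 2.55e-28) and 6 falls (1.039 expected, p = 0.000483) among 6472 genes tested in both. The shared rises held Ndufa4l2, Vegfa, Apln, Adm, C4b, Pfkp, the stress regulator Nupr1, the cholesterol exporter Abca1 and the lactate transporter chaperone Bsg, and the shared falls held Slco1c1, the opioid precursor Pdyn and Pde4b. Of 67 Ribotag rises in that set 52 were also above 0 in single cells, and of 217 falls 104 were below 0. Of all genes in the set 48.7 percent lay above 0 and 51.3 percent below 0 in single cells. The Ribotag falls as a group thus did not share their direction beyond that base. Across all genes the Pearson correlation was 0.121 and the Spearman correlation -0.0161, against 0.16 and 0.132 for whole retina with single Müller glia. Eif2s3y, a Y-linked gene, rose in Ribotag RNA and fell in single cells (-1.14 log2, edgeR adjusted p = 0.0309).

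**Figure D2:**
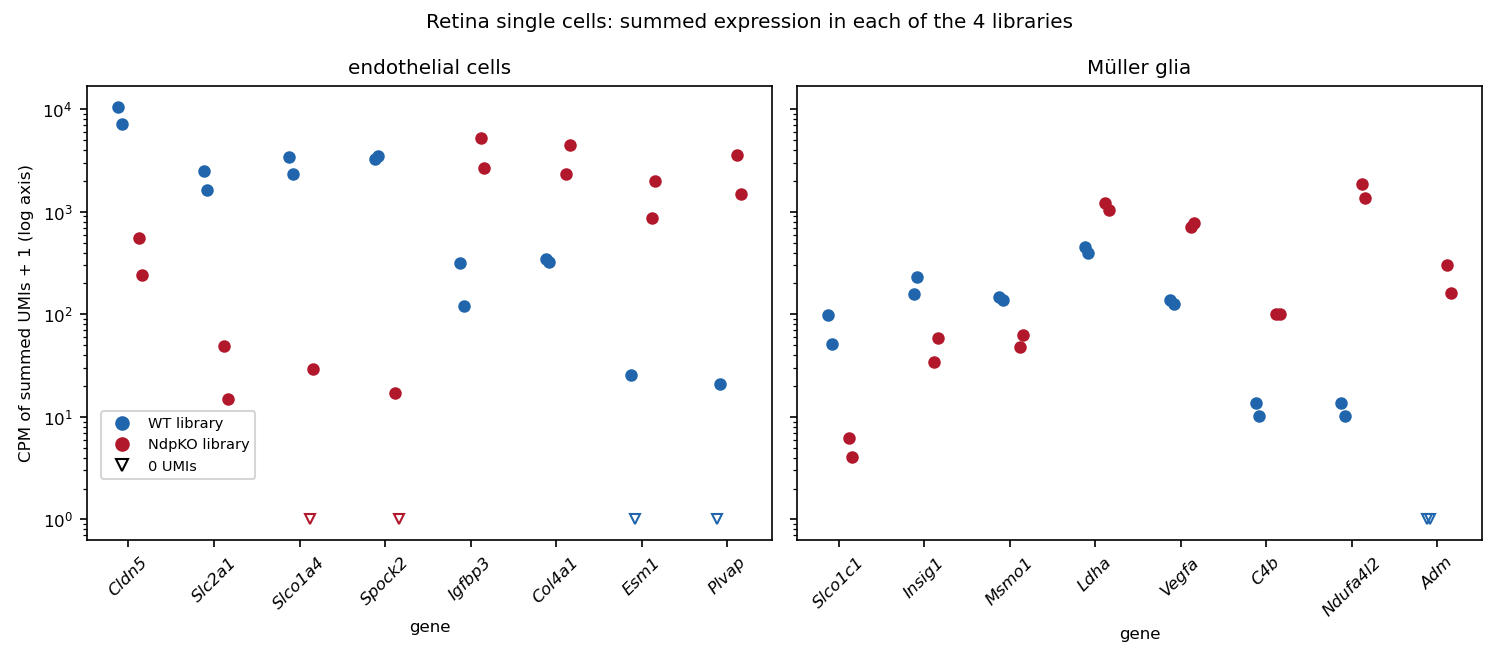
CPM + 1 on a log axis for 8 genes in retinal endothelial cells and 8 in Müller glia, with a point per library (n = 2 per genotype) and an open triangle for 0 UMIs. Endothelial Cldn5 stood at 8879 CPM in WT and 397 CPM in NdpKO, and Müller Vegfa at 130.0 and 746 CPM.

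In retinal endothelial cells of NdpKO mice several single genes of the blood-retina barrier were lower. Cldn5 (16:18776847-18778262), the main claudin of neural endothelium, fell from 8879 ± 2377 to 397 ± 223 CPM (-4.49 log2, SE 0.42, edgeR adjusted p = 0.000223, n = 2 and 2). Slc2a1 (4:119108711-119137983), the barrier glucose transporter, fell from 2072 ± 612 to 30.8 ± 23.7 CPM (-6.01 log2, SE 0.57, adjusted p = 0.000223). Plvap, the diaphragm protein of leaky endothelium, was higher by a ratio of 222 (counting interval 39.6 to 8800, adjusted p = 0.00049), and Esm1, a tip cell proteoglycan, by 132 (23.4 to 5230). Of 9 Norrin and beta-catenin target genes 7 fell (median -3.97 log2, camera adjusted p = 2.71e-06, adjusted p = 0.623 with an estimated correlation), with Foxq1 at least 39.3-fold, Slco1c1 at least 30.4-fold and Mfsd2a, a lipid transporter, at least 17.9-fold lower. Slco1a4 stood at a ratio of 0.00525 (0.000632 to 0.0192, adjusted p = 0.000173), Spock2 at 0.00217 (5.48e-05 to 0.0122, adjusted p = 4.17e-05), and the tight junction genes Lsr and Ocln were at least 29.9-fold and 12.5-fold lower. Of 9 tip cell genes 6 rose (camera adjusted p = 6.63e-05, adjusted p = 0.623 with an estimated correlation). Igfbp3 stood at 219.6 ± 141 and 3995 ± 1843 CPM (4.21 log2, SE 0.51, adjusted p = 0.000852). Of 8 basement membrane genes 7 rose and 1 fell (camera adjusted p = 0.00022, adjusted p = 0.623 with an estimated correlation), with Col4a1 at 332 and 3414 CPM (3.36 log2, SE 0.42, adjusted p = 0.000852). Of 1609 genes tested 177 passed. This class was tested after the data were seen, with a lower minimum of 10 cells, and its smallest NdpKO library had 13 cells (median 5613 UMIs) against 31 in the smaller WT library (median 1116).

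Perivascular and horizontal cells, tested by the same later choice, gave shorter sets. In perivascular cells Vtn, vitronectin, fell from 16990 ± 437 to 463 ± 111 CPM (-5.11 log2, SE 0.29, edgeR adjusted p = 6.08e-05, n = 2 and 2). Of 13 pericyte and smooth muscle markers 3 fell and 0 rose (5 and 2 over the list alone, camera adjusted p = 0.0548, adjusted p = 0.696 with an estimated correlation). The falls were of Vtn, Kcnj8, a potassium channel (-2.91 log2, adjusted p = 0.0471), and the receptor Pdgfrb (-1.70 log2, adjusted p = 0.0307), while the pericyte gene Rgs5 stood at 14460 and 14470 CPM (adjusted p = 0.999). Pln, phospholamban, had 0 UMIs in WT and 66 in NdpKO (adjusted p = 0.0241), and S100a6 rose by 3.64 log2 (adjusted p = 0.00258). A different mix of pericytes and smooth muscle cells in this small class was not excluded. In horizontal cells 10 of 14 glycolytic genes rose (12 over the list alone, median 0.77 log2, camera adjusted p = 9.90e-25, adjusted p = 0.139 with an estimated correlation). Ldha stood at 758 and 2415 CPM (1.68 log2, SE 0.18, adjusted p = 9.2e-06), Gpi1 at 839 and 2469 CPM (1.56 log2, SE 0.16, adjusted p = 9.2e-06) and Pfkp at 2.31 log2 (adjusted p = 0.00135). The autophagy gene Bnip3 rose by 1.51 log2 (adjusted p = 0.00129) and Npy, a neuropeptide, fell by 1.81 log2 (adjusted p = 0.0116).

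In bipolar cells of NdpKO retina some hypoxia, glycolysis and immediate early genes were higher. Cox4i2, a cytochrome oxidase subunit induced by low oxygen, rose from 19.7 to 222 CPM (3.49 log2, SE 0.21, edgeR adjusted p = 3.61e-06, n = 2 and 2). The hexokinase Hk2 rose from 55.6 to 232 CPM (2.07 log2, adjusted p = 8.17e-05) and Egln3, an oxygen sensor that is itself a HIF target, by a ratio of 66.0 (counting interval 18 to 548, adjusted p = 0.000227). Of 24 hypoxia-inducible genes 13 rose (22 over the list alone, median 1.02 log2, camera adjusted p = 2.67e-31, adjusted p = 0.361 with an estimated correlation). Of 18 glycolytic genes 8 rose (15 over the list alone, camera adjusted p = 9.85e-22, adjusted p = 0.361 with an estimated correlation). Of 14 immediate early genes 7 rose (12 over the list alone, camera adjusted p = 4.90e-19, adjusted p = 0.320 with an estimated correlation). Egr1 stood at 1.92 log2 (adjusted p = 0.000265), Junb at 1.62 log2 (adjusted p = 0.000383) and Fos at 1.24 log2 (adjusted p = 0.00579). Falls included the neuropeptide Cck (from 421 to 173 CPM, -1.28 log2, SE 0.16, adjusted p = 0.00127), Bdnf (-1.12 log2, adjusted p = 0.00847) and Marcksl1 (-2.25 log2, adjusted p = 0.00711). H2-Ab1, an antigen-presenting molecule of immune cells, rose from 1.16 to 55.1 CPM (5.53 log2, SE 0.39, adjusted p = 1.45e-05). In this class 5 of 18 Müller markers rose and 1 fell, and 3 of 5 microglia markers rose, with C1qa at 2.81 log2 (adjusted p = 0.0267) and Apoe at 2.20 log2 (adjusted p = 8.63e-05). In all, 140 of 10293 genes passed, 100 with a rise.

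Split after the data were seen, rod bipolar cells showed 14 of 18 glycolytic genes higher (median 1.25 log2, camera adjusted p = 2.87e-39, adjusted p = 0.253 with an estimated correlation). Aldoc stood at 73.1 and 561 CPM (2.94 log2, edgeR adjusted p = 1.28e-07, n = 2 and 2), Hk2 at 10.5 and 177 CPM (4.17 log2, adjusted p = 8.01e-07) and Bnip3 at 148 and 731 CPM (2.31 log2, adjusted p = 8.01e-07). Cone bipolar cells showed 3 of 18. Cox4i2 rose in rod bipolar cells by 5.78 log2 (SE 0.48, adjusted p = 1.28e-07). Kcne2, a potassium channel subunit, rose in cone bipolar cells by 3.57 log2 (adjusted p = 1.24e-07). The difference between the subclasses was not tested.

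In amacrine cells some sterol synthesis genes were lower. Of 18 genes 6 fell (15 over the list alone, median -1.08 log2, camera adjusted p = 8.86e-27, adjusted p = 0.328 with an estimated correlation). Fdps stood at 227 CPM in WT and 71.9 CPM in NdpKO (-1.68 log2, SE 0.17, edgeR adjusted p = 0.00338, n = 2 and 2), Idi1 at -1.46 log2 (adjusted p = 0.00591) and Hmgcs1 at -1.38 log2 (adjusted p = 0.00747). Vgf, a neuropeptide precursor, fell from 76.7 to 19.0 CPM (-2.002 log2, SE 0.20, adjusted p = 0.00338), and Mt2 rose from 83.7 to 317 CPM (1.91 log2, SE 0.20, adjusted p = 0.00364). Of 24 hypoxia-inducible genes 2 rose (11 over the list alone, camera adjusted p = 2.73e-10, adjusted p = 0.328 with an estimated correlation). In all, 45 of 11495 genes passed.

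Fewer genes passed in photoreceptors and ganglion cells. Cell numbers and depth differed between classes and libraries, so these counts do not rank the responses. Rods held 3606743 and 206591 UMIs in the NdpKO libraries, and ganglion cells numbered 20 in the smallest library. In rods Edn2 rose from 11.02 ± 5.86 to 71.6 ± 13.9 CPM (2.77 log2, SE 0.38, edgeR adjusted p = 0.000779, n = 2 and 2) and Fgf2, a survival factor, by 2.05 log2 (adjusted p = 0.0368). Bnip3 rose from 83.3 to 288 CPM (1.83 log2, SE 0.22, adjusted p = 0.000129) and Fxyd6, a regulator of the sodium pump, from 3.13 to 59.2 CPM (4.27 log2, SE 0.49, adjusted p = 8.23e-05). Of 16 hypoxia-inducible genes 4 rose in rods (10 over the list alone, camera adjusted p = 2.49e-10, adjusted p = 0.281 with an estimated correlation), and 35 of 7063 genes passed. In cones Fxyd6 rose by a ratio of 19.2 (counting interval 5.12 to 162, adjusted p = 2.22e-05) and Mt1 by 1.82 log2 (adjusted p = 6.98e-06). In all, 15 of 5541 genes passed, and 1 passed when only cells of at least 1000 UMIs were kept. In ganglion cells Apoe (2.70 log2, adjusted p = 0.0085) and the tachykinin precursor Tac1 (2.54 log2, adjusted p = 0.0085) rose and Adcyap1, a neuropeptide, fell (-3.91 log2, adjusted p = 0.0304). The Müller markers Apoe, Clu and Rlbp1 rose in rods (2.04, 1.34 and 2.15 log2), where 4 of 10 such markers passed, and 3 of 8 passed in cones.

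Müller glia made up 6.85 ± 1.64 percent of kept NdpKO cells and 3.77 ± 0.526 percent of WT cells (n = 2 and 2), and microglia 1.00 ± 0.163 and 0.283 ± 0.0876 percent, with no overlap between genotypes. Endothelial cells made up 0.380 ± 0.294 and 0.945 ± 0.126 percent and horizontal cells 0.610 ± 0.168 and 0.366 ± 0.0677 percent, also without overlap. All other classes overlapped among kept cells. With 2 libraries per genotype a lack of overlap is frequent by chance, so no share was called. Rods ranged from 9.19 to 54.1 percent in the NdpKO libraries, which sets the total for every other class. With rods left out and all annotated barcodes kept, Müller glia made up 13.4 percent in NdpKO and 6.35 percent in WT. In that setting cone bipolar cells made up 25.55 and 31.74 percent and rod bipolar cells 11.34 and 13.18 percent, lower in NdpKO without overlap, while in the main setting both overlapped.

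Whole brain after 48 h of hypoxia had higher Vegfa (from 24.8 ± 0.659 to 60.1 ± 10.5 TPM, 1.032 log2, SE 0.12, limma adjusted p = 0.00134, n = 3 and 3) and higher levels of single genes of endothelium. Cd93, a receptor of sprouting endothelium, rose from 1.83 ± 0.183 to 10.6 ± 3.28 TPM (1.80 log2, SE 0.21, adjusted p = 0.00178), and Ctla2a, a protease inhibitor, from 13.7 ± 3.06 to 57.9 ± 6.56 TPM (1.82 log2, SE 0.14, adjusted p = 0.000237). The metalloprotease Adamts1 rose to 17.9 ± 3.69 TPM (1.71 log2, SE 0.19, adjusted p = 0.00178) and Cldn5 from 10.7 ± 2.47 to 25.9 ± 6.204 TPM (1.00 log2, SE 0.19, adjusted p = 0.00975). The other leading rises were of AC127349.1, AC153948.2 and AC154176.1, genes without an assigned function (4.92, 1.53 and 1.41 log2), and the falls of the histone gene Hist1h4b (-1.31 log2, adjusted p = 0.00178), the chaperone gene Dnajb5 (-1.23 log2), Ugt8a (-1.05 log2), which makes myelin lipid, and Osgep (-1.01 log2). Of 22 endothelial markers 6 rose and 1 fell (10 and 2 over the list alone, camera adjusted p = 0.424). Arc and Egr1, neuronal activity genes, fell, with changes of -1.82 log2 (SE 0.39, adjusted p = 0.0435) and -1.01 log2 (SE 0.17, adjusted p = 0.0259).

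At 48 h 9 of 27 hypoxia-inducible genes rose and 0 fell (15 and 1 over the list alone, camera adjusted p = 0.00309). Of 18 glycolytic genes 7 rose (10 over the list alone, camera adjusted p = 0.000115) and of 20 tip cell genes 7 (13 over the list alone, camera adjusted p = 0.00118). Each of these lists had adjusted p = 0.878 with an estimated correlation. Examples were Bnip3 (from 58.2 to 102 TPM, 0.61 log2, adjusted p = 0.0023), Gpi1 (0.49 log2, adjusted p = 0.00751), Apln (from 7.64 to 18.7 TPM, 0.99 log2, adjusted p = 0.00235), Igfbp3 (0.74 log2, adjusted p = 0.00751) and Plaur, the urokinase receptor (1.29 log2, adjusted p = 0.0023). Of 17 gliosis genes 4 rose (7 over the list alone, camera adjusted p = 0.0739), among them Vim (from 35.3 to 67.4 TPM, 0.72 log2, adjusted p = 0.0136) and C4b (0.74 log2, adjusted p = 0.0174). Heat shock genes fell in 2 of 11 cases (6 over the list alone, median -0.55 log2, camera adjusted p = 1.01e-12) and immediate early genes in 2 of 16 (4 over the list alone, camera adjusted p = 5.14e-09), both with adjusted p = 0.878 with an estimated correlation. The chaperones Hsph1 and Hspa5 changed by -0.98 and -0.84 log2 (adjusted p = 0.0164 and 0.0473), and Cryab, a small heat shock protein, fell from 71.4 to 42.4 TPM (-0.92 log2, adjusted p = 0.0148). Nuclear genes for oxidative phosphorylation gave 0 calls among 70, a median of 0.06 log2 before and -0.13 log2 after subtraction of the all-gene median, and a camera call of a fall (adjusted p = 0.0281, adjusted p = 0.878 with an estimated correlation).

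After 7 d of hypoxia some endothelial, pericyte and glial genes were higher in brain. Vegfa stood at 68.5 ± 4.29 TPM (1.25 log2, SE 0.12, limma adjusted p = 6e-04, n = 3 and 3). Ndufa4l2 rose from 1.82 ± 0.175 to 9.20 ± 2.04 TPM (1.66 log2, SE 0.17, adjusted p = 0.000646) and Apoc1 (7:19689481-19692660), a lipoprotein component, from 2.01 ± 0.679 to 14.0 ± 0.687 TPM (2.17 log2, SE 0.17, adjusted p = 0.000271). Vwf, von Willebrand factor, rose from 3.32 to 13.6 ± 4.08 TPM (1.55 log2, SE 0.27, adjusted p = 0.00613) and Apod, a lipocalin, from 159.5 ± 5.92 to 515.8 ± 137 TPM (1.48 log2, SE 0.15, adjusted p = 0.000646). Cryab fell from 71.4 ± 12.3 to 31.1 ± 3.24 TPM (-1.34 log2, SE 0.12, adjusted p = 0.00149).

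Of 22 endothelial markers 11 rose at 7 d (17 over the list alone, median 0.52 log2, camera adjusted p = 1.06e-07, adjusted p = 0.566 with an estimated correlation). Cldn5 stood at 25.8 ± 3.35 TPM (1.04 log2, adjusted p = 0.00601), Slco1a4 at 0.58 log2 (adjusted p = 0.00507) and Igfbp7 at 0.90 log2 (adjusted p = 0.00335). Of 13 pericyte markers 6 rose (8 and 1 fall over the list alone, camera adjusted p = 0.00453, adjusted p = 0.566 with an estimated correlation), with Rgs5 at 0.89 log2 (adjusted p = 0.00137) and Kcnj8 at 0.67 log2 (adjusted p = 0.00583). The VEGF receptor Kdr rose by 1.47 log2 (adjusted p = 0.00503) and the collagen Col4a1 by 1.02 log2 (adjusted p = 0.0414). Hypoxia-inducible genes rose in 8 of 27 cases (11 over the list alone, camera adjusted p = 0.00124), glycolytic genes in 7 of 18 (9 over the list alone, camera adjusted p = 0.000178) and gliosis genes in 7 of 17 (9 over the list alone, camera adjusted p = 7e-05). Each list had adjusted p = 0.566 with an estimated correlation. Among them were Bnip3 (0.68 log2, adjusted p = 0.00137), Ldha (0.30 log2, adjusted p = 0.0218), C4b (from 5.88 ± 0.344 to 20.4 ± 5.73 TPM, 1.43 log2, SE 0.17, adjusted p = 0.00143), S100a6 (0.96 log2, adjusted p = 0.00259) and the protease inhibitor A2m (1.37 log2, SE 0.14, adjusted p = 0.000646). Glutathione genes rose in 4 of 16 cases (7 over the list alone, camera adjusted p = 0.00546, adjusted p = 0.566 with an estimated correlation), with Nqo1 at 0.68 log2 (adjusted p = 0.00623) and Hmox1 at 0.76 log2 (adjusted p = 0.0152). Of 4 neutrophil and monocyte markers 3 rose (camera adjusted p = 0.00453, adjusted p = 0.566 with an estimated correlation), with S100a9 at 1.91 log2 (adjusted p = 0.0236) and S100a8 at 1.96 log2 (adjusted p = 0.0309).

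Sterol synthesis genes fell in 2 of 18 cases at 7 d and in 8 with 1 rise over the list alone (median -0.43 log2, camera adjusted p = 1.09e-12, adjusted p = 0.566 with an estimated correlation). Msmo1 stood at -1.0035 log2 (adjusted p = 0.0104) and Hmgcs1 at -0.77 log2 (adjusted p = 0.0147). Heat shock genes fell in 3 of 11 cases (7 over the list alone, median -0.65 log2, camera adjusted p = 2e-15, adjusted p = 0.566 with an estimated correlation), Hsph1 from 76.1 to 35.2 TPM (-1.26 log2, adjusted p = 0.00293). Median-of-ratios scaling gave 12 falls among the sterol genes and 8 among the heat shock genes. Dio2 fell from 14.0 to 6.402 TPM (-1.20 log2, adjusted p = 0.00335). Fabp7, a fatty acid carrier of astrocytes and progenitors, fell from 38.0 to 18.5 TPM (-1.18 log2, adjusted p = 0.00601) and Mfge8, a bridge for phagocytosis, from 39.0 to 17.7 TPM (-1.27 log2, adjusted p = 0.00176). The ceramidase Acer2 rose by 1.37 log2 (adjusted p = 0.000646), and S100a5 fell (-1.26 log2, adjusted p = 0.0221). Of 16 microglia markers 1 fell, Tmem119 (-0.79 log2, adjusted p = 0.0204), and of 14 neuron markers 2 fell, among them Nefl (-0.67 log2, adjusted p = 0.0107). For the neuron markers the median was 0.06 log2 before subtraction and -0.12 log2 after it, and camera called a fall (adjusted p = 0.0206, adjusted p = 0.597 with an estimated correlation).

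At 48 h 1003 of 20397 genes passed and at 7 d 944, of which 90.9 and 89.2 percent rose. After rescaling to protein-coding genes the shares of rises were 61.3 and 71.0 percent, and by median of ratios 52.8 and 57.2 percent. The small nuclear and cytoplasmic RNAs 7SL and 7SK took 44.1 to 50.9 percent of TPM in the brain libraries. Leaving out the second normoxia library left 119 genes at 48 h, and leaving out the third 7 d library left 234 at 7 d.

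Between 7 d and 48 h, 7 genes differed, 5 higher at 7 d. Apoc1 (1.35 log2, SE 0.17, limma adjusted p = 0.0339, n = 3 and 3), the lectin Clec2d (from 3.48 to 10.2 ± 2.29 TPM, 1.31 log2, SE 0.16, adjusted p = 0.0303) and the chemokine Cxcl12 (from 7.53 to 19.7 TPM, 1.28 log2, SE 0.17, adjusted p = 0.0455) rose, as did the barrier transporters Slco1a4 (from 21.8 ± 0.897 to 42.9 TPM, 0.95 log2, SE 0.11, adjusted p = 0.0303) and Slc16a1 (0.92 log2, adjusted p = 0.0371). With a replicate block, and also without the first 48 h library, 0 genes were called higher at 7 d. Of 22 endothelial markers 7 rose over the list alone (median 0.20 log2, camera adjusted p = 2.81e-10, adjusted p = 0.393 with an estimated correlation). The 48 h and 7 d comparisons shared 475 rises (37.65 expected) and 39 falls (0.4551 expected, Fisher p = 2.98e-68), with 1 gene in opposite directions (8.317 expected). They also shared the normoxia libraries and the estimate of spread per gene. In 20 simulations with no change the mean number of shared calls was 0 and the correlation 0.5, against 0.698 in the data. The simulated covariance was 0.0185 against 0.0561 in the data, so part of the excess may come from shared controls. With no change simulated hardly any gene can be called. The 0 shared calls therefore do not show how many the shared controls add to real calls. The simulations also held no shift in the median of all genes.

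**Figure D3:**
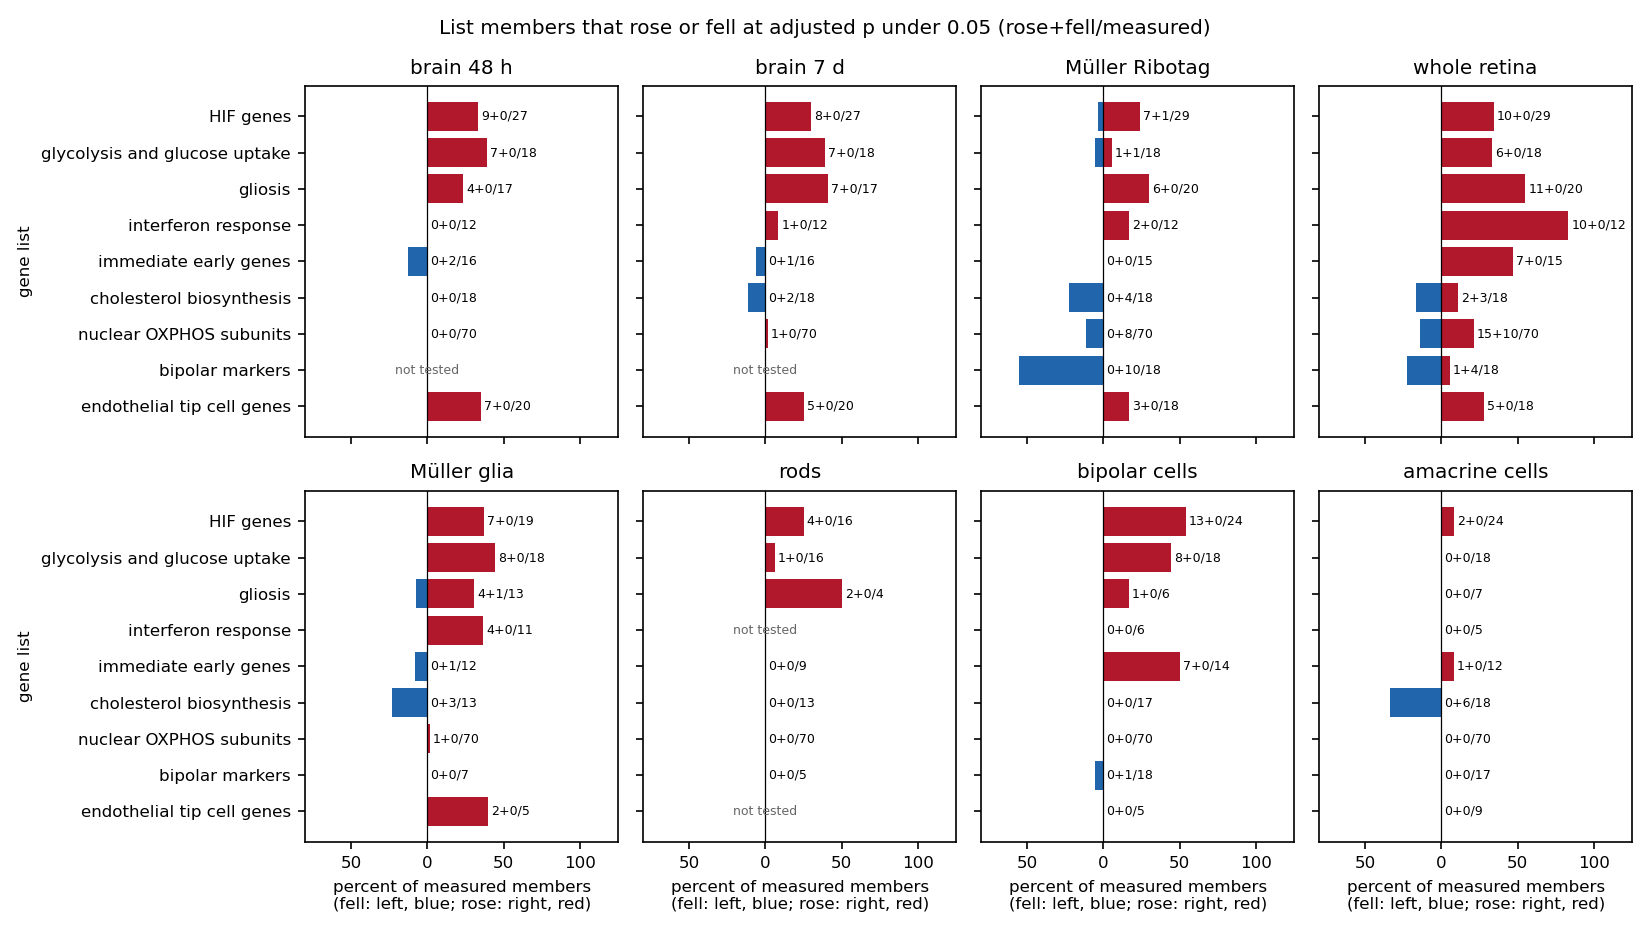
Percent of measured members that rose or fell (adjusted p below the threshold over all genes) for 9 gene lists in 8 comparisons, with bars to the right for rises and to the left for falls. Hypoxia-inducible genes rose in 9 of 27 cases in brain at 48 h, 10 of 29 in whole retina and 13 of 24 in bipolar cells.

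Calls in brain at 7 d and in Müller Ribotag RNA shared 25 rises, with 20.43 expected by chance (Fisher p = 0.174), and 4 falls (1.694 expected, p = 0.0899), while 25 genes went in opposite directions (16.73 expected). At 48 h there were 19 shared rises (22.55 expected, Fisher's exact p = 0.81) and 0 shared falls (1.452 expected). The rises shared at 7 d held Vegfa, Ndufa4l2, Apln, C4b, A2m, Hmox1, Serpina3n, Osmr, the cytokine receptor of oncostatin M, and Abca1. Brain at 7 d and whole retina shared 97 rises (79.55 expected, Fisher's exact p = 0.0224) and 1 fall (7.122 expected), with 69 genes in opposite directions (69.6 expected) and a correlation across all genes of -0.0614.

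In cortex, 1 library of each condition was compared, so no spread between libraries could be measured, and values describe those libraries and not the conditions. The treatment tags of these libraries were the reverse of their titles and source names, which were used here, and a swap would turn every sign. In endothelial cells of the library labelled hypoxia, 327 of 438 genes that rose in brain at 7 d were higher and 45 of 60 that fell were lower. The median of all genes compared in that class was 0.0163 log2. In every class compared the Pearson correlation with the brain change was positive, from 0.1056 (oligodendrocyte precursors) to 0.3018 (glutamatergic neurons). A swap would make these correlations negative. Angpt2, a tip cell ligand of Tie2, stood at 300.1 and 1.48 CPM in hypoxia and normoxia endothelial cells (ratio 202, 95 percent counting interval 69.0 to 983), Apln at 240.3 and 4.95 CPM (48.6, 26.3 to 102), and Adm at 121 and 19.3 CPM (6.27). Pkm and Ldha stood at ratios of 4.02 and 3.80. Gkn3 stood at 34.8 and 239 CPM. Hemoglobin RNA also differed, with Hbb-bs at 1800 CPM in all kept cells of the hypoxia library and 16.6 CPM in the normoxia library.

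Lists were set against 10000 random lists matched for level, as a description. Tip cell genes had a median of 1.62 log2 in endothelial cells, with 18 of 22 counting intervals above a ratio of 1 and 1 below (percentile 100). They were also high in astrocytes (1.04 log2), microglia (1.04 log2) and glutamatergic neurons (0.74 log2). In the endothelial class markers of pericytes and smooth muscle (0.82 log2, 9 of 13 above), neuron markers (0.65 log2, 7 of 13 above) and hemoglobin genes (7.61 log2) were higher too, so a shift shared by the whole library or RNA from other cells was not excluded. Glycolytic genes had a median of 1.06 log2 in endothelial cells, with 14 of 18 above and 2 below (percentile 100), and a median above 0 in all 11 classes. Hypoxia-inducible genes stood at 0.69 log2 in endothelial cells, 14 of 29 above and 3 below, and at 0.41 log2 after thinning. Heat shock genes were lower in ependymal cells (-1.08 log2, 9 of 11 below) and oligodendrocytes (-0.63 log2, 9 of 11 below). Sterol synthesis genes were lower in astrocytes (-0.48 log2, 12 of 18 below, percentile 0) and higher in pericytes (0.86 log2, 6 of 16 above). Interferon-response genes stood at 0.77 log2 in microglia, 7 of 12 above. In that class all 16 microglia markers were lower (-0.33 log2), 54 of 54 ribosomal protein genes higher (0.57 log2) and neutrophil and monocyte markers higher (1.16 log2, 2 of 3 above), so a changed makeup of the class was not excluded.

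Astrocytes of the hypoxia library had Vegfa at 611 and 185 CPM (ratio 3.30, 2.95 to 3.70), C4b at 86.8 and 21.97 CPM (3.95, 2.87 to 5.52) and Ndufa4l2 at 139.9 and 44.8 CPM, with Pde10a at 136 and 510.3 CPM (0.267) and Dio2 at 82.2 and 213 CPM (0.386) lower. Smooth muscle cells had Ndufa4l2 at 2975 and 574 CPM (5.18) and pericytes Lgals1, a galectin, at 1315 and 331 CPM (3.98). Microglia had H2-Eb1, an antigen-presenting molecule, at 364 and 67.0 CPM (5.44, 4.62 to 6.43). Oligodendrocytes had the cold-induced RNA-binding protein Rbm3 at 358 and 66.1 CPM, Ldha at 386 and 75.2 CPM (5.13) and Cryab at 2492 and 5451 CPM (0.457). Ependymal cells had Gfap at 329 and 104.5 CPM (3.15) and the chaperone Hsp90aa1 at 2237 and 5503 CPM (0.407). Neural progenitors had Car1, a carbonic anhydrase of red cells, at 1032 CPM (371 UMIs) against 0 UMIs.

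**Figure D4:**
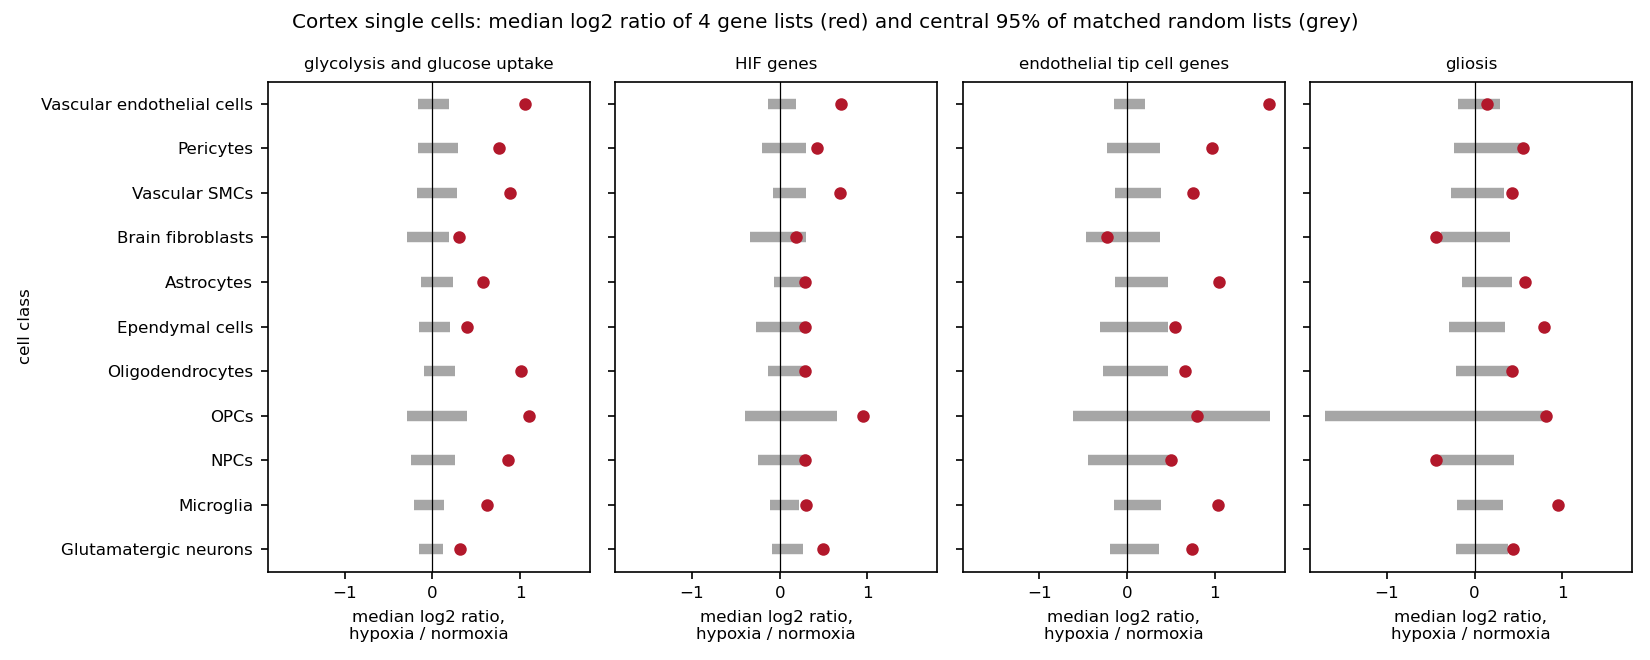
Median log2 ratio of hypoxia to normoxia CPM for 4 gene lists in 11 cortical cell classes (1 library per condition), with the central 95 percent of 10000 matched random lists as a line. Endothelial tip cell genes stood at 1.62 log2 and glycolytic genes at 1.06 log2.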

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

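No test in this part was chosen after its result was seen, and the rule that picked these genes was set before the data were examined. The genes below differed between groups that the other comparisons treat alike, and their values are given without subtraction of the all-gene median, from limma with n = 3 per brain group and n = 2 per retinal group.

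Between 7 d and 48 h of hypoxia the difference in brain was 1.347 log2 for Apoc1, which rose by 1.00 log2 at 48 h (adjusted p = 0.0136) and by 2.35 log2 at 7 d (adjusted p = 0.000271). Clec2d differed by 1.307 log2, with -0.63 log2 at 48 h (adjusted p = 0.0453) and 0.68 log2 at 7 d (adjusted p = 0.0359), so its direction turned. Cxcl12 differed by 1.28 log2 and rose at 7 d (1.21 log2, adjusted p = 0.00507) but had no call at 48 h (adjusted p = 0.808). The barrier transporter Slco1a4 differed by 0.95 log2, with -0.19 log2 at 48 h (adjusted p = 0.281) and 0.76 log2 at 7 d (adjusted p = 0.00507), and the lactate transporter Slc16a1 differed by 0.92 log2. With a replicate block 0 of these were called.

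The genotype effect differed most between Ribotag RNA and whole retina for genes of no assigned function and for pseudogenes. AY036118 differed by 11.50 log2 (adjusted p = 0.000105), all of it in Ribotag RNA, and AC131720.2, AC156576.2 and AC159747.1 by 9.08, 7.90 and 7.88 log2 (adjusted p = 0.00805, 0.00803 and 0.0105). AA465934 differed by 9.49 log2 (adjusted p = 0.00167), most of it a fall of -7.97 log2 in whole retina, and AC158392.1 by 8.26 log2 (adjusted p = 0.0156). Rps3a2 differed by -10.78 log2 (adjusted p = 0.00785), with -6.29 log2 in Ribotag RNA and 4.49 log2 in whole retina, and Rpl19-ps11 by -7.95 log2 (adjusted p = 0.000118). Pgk1-rs7 (-7.36 log2), Cbx3-ps6 (-7.00 log2) and Rpl38-ps2 (-6.78 log2) differed through a rise in whole retina alone. Rps13-ps1 differed by -7.54 log2, with -0.83 log2 in Ribotag RNA (adjusted p = 0.392) and 6.70 log2 in whole retina.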

How the results depend on the processing

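Most settings were chosen before the data were examined, and rescaling to protein-coding genes, median-of-ratios scaling, all annotated barcodes and rods left out of the total were chosen after seeing the data. The cause of a moved count was not tested. For 425 called values of named genes, recomputed with the settings chosen in advance, 2928 of 3809 recomputed values kept their call, 881 lost it and 0 turned. Most of these losses came with a library left out. With the settings added after the data were seen, 512 called values were recomputed, of planned comparisons and of classes tested later. Of 1369 recomputed values 1259 kept the call, 110 lost it and 0 turned.

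Without the filter on low values the number of genes called moved from 1003 to 463 in brain at 48 h, from 944 to 491 at 7 d, from 7 to 11 between 7 d and 48 h, from 3946 to 2572 in whole retina, from 3325 to 1900 for the difference between the genotype effects, from 96 to 235 in Müller glia, from 35 to 58 in rods, from 140 to 319 in bipolar cells, from 45 to 283 in amacrine cells and from 3 to 28 in ganglion cells. The brain 48 h and 7 d overlap of calls moved with it from 514 to 224 genes, and the brain 7 d and Muller ribotag overlap of calls from 29 to 13. Rescaling to protein-coding genes gave 1901 calls at 7 d, 61 between the times and 916 and 100 in the overlaps, and median of ratios gave 1760, 16, 888 and 73. A pseudocount of 0.1 gave 762 calls in Müller Ribotag RNA. A fit of only the groups compared gave 600 calls at 7 d and 104 in Müller Ribotag RNA.

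A replicate block gave 377 calls at 48 h, 466 at 7 d, 2 between the times and 210 shared calls. Replicate numbers did not pair libraries in the residuals, with correlations of -0.164 and 0.332 between same-numbered normoxia and hypoxia libraries of number 1.

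By the DESeq2 Wald test 55 genes were called in Müller glia, 10 in rods, 1 in cones, 79 in bipolar cells and 1 in ganglion cells. In endothelial cells it called 108 in place of 177, at the minimum of 10 cells chosen after seeing the data. At that minimum it called 7 in place of 16 in perivascular cells and 11 in place of 34 in horizontal cells. After the later split it called 34 in place of 87 in rod bipolar cells and 56 in place of 133 in cone bipolar cells. Thinning each cell to 500 UMIs gave 2 in cones, 36 in bipolar cells, 15 in amacrine cells and 1 in ganglion cells (0 of the 3 main calls), and moved the median of hypoxia-inducible genes in cortical endothelial cells from 0.6946 to 0.4106 log2. Cells of at least 1000 UMIs gave 1 call in cones and all annotated barcodes 3. With rods left out of the total the difference in the share of Müller glia was 7.075 points in place of 3.086. With an estimated correlation 0 of 416 list tests in 13 comparisons were called in place of 184. That total leaves out the retinal classes tested after the data were seen, in which 0 were called with an estimated correlation. In that setting not even the 23 Müller glia markers, all higher in wild-type Ribotag RNA than in whole retina, were called (camera adjusted p = 0.108). With so few libraries the setting may have little power, so a missing call there is not evidence against a list.

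Leaving out each library in turn gave 119 to 744 calls in brain at 48 h, 234 to 1573 at 7 d and 1 to 12 between the times. It gave 7 to 5001 in Müller Ribotag RNA, 656 to 2093 in whole retina, 184 to 6149 for the difference of genotype effects and 1659 to 2354 between wild-type Ribotag RNA and whole retina. In single cells the range was 80 to 293 in Müller glia, 7 to 68 in rods, 1 to 13 in cones, 30 to 284 in bipolar cells, 57 to 192 in amacrine cells and 3 to 18 in ganglion cells. The overlaps ranged from 95 to 595 and from 2 to 39. The extremes at 48 h came without the second normoxia and second 48 h library, at 7 d without the third and the first 7 d library, and in Müller Ribotag RNA without the second WT and the first NdpKO library.

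Not run were count models on bulk TPM and on the overlaps built from it, multiplets kept in the class tests, rods at 1000 UMIs (7 cells in the smallest library), and the planned tests of endothelial (13 cells), perivascular (11), horizontal (12), microglial (8) and astrocytic (8) classes at the minimum of 20 cells.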

Other observations

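Metallothioneins and transcripts of the mitochondrial genome moved in several comparisons. In brain at 48 h of hypoxia 2 of 3 metallothioneins rose (median 0.76 log2 relative to all genes, n = 3 and 3, camera adjusted p = 0.125), and in amacrine cells of NdpKO retina 2 of 3 rose. In the cortex library labelled hypoxia they were lower in most classes, with medians of -1.18 log2 in endothelial cells, -0.61 log2 in microglia and -0.59 log2 in glutamatergic neurons (3 of 3 counting intervals below a ratio of 1 in each). Mitochondrially encoded genes rose in 3 of 13 cases at 48 h (8 over the list alone), with mt-Nd1, a complex I subunit, at 0.26 log2 (limma adjusted p = 0.0361), and in 0 of 13 cases at 7 d, and 11 of 13 fell between 48 h and 7 d over the list alone (median -0.38 log2, adjusted p = 0.366 with an estimated correlation). In whole NdpKO retina 6 of 13 rose and 2 fell, with mt-Nd2 at 3.70 log2 (adjusted p = 0.00219).

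Calls among immediate early genes differed in sign between comparisons, which were not tested against each other. Of these genes 2 of 16 fell in brain at 48 h (adjusted p = 0.878 with an estimated correlation), while 7 of 15 rose in whole NdpKO retina and 7 of 14 in bipolar cells. In single Müller glia 1 of 12 fell (median -0.49 log2, camera adjusted p = 4.18e-05, adjusted p = 0.477 with an estimated correlation), with the phosphatase Dusp1 at -1.28 log2 (edgeR adjusted p = 0.012, n = 2 and 2). In the cortex library labelled hypoxia their median lay below the range of matched random lists in neural progenitors (-0.91 log2) and endothelial cells (-0.24 log2) and within it in the other 9 classes. Neural progenitors numbered 62 in hypoxia and 180 in normoxia, and their neuroblast markers were lower as well (-0.58 log2, 9 of 11 counting intervals below a ratio of 1).

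The comparisons below with bipolar markers in wild-type Ribotag RNA and with other marker lists, the test of bipolar shares and the splits of libraries were chosen after the result was seen. The excess of rises among brain calls may reflect expression or the few small RNAs that took a large part of the TPM. After rescaling to the protein-coding total, rises made up 61.3 percent of the calls at 48 h and 71.0 percent at 7 d, and by median of ratios 52.8 and 57.2 percent. On rescaling, the rises went from 912 to 903 and from 842 to 1350 and the falls from 91 to 569 and from 102 to 551, in a smaller set of genes, so these explanations cannot be told apart. The real grouping, 1 of the 10 splits of the 6 libraries into 3 and 3, gave 821 calls at 48 h (highest other 7), 600 at 7 d (highest other 17) and 8 between the times (highest other 5), and 10 splits are too few for a share under 0.05.

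The lower bipolar markers in Müller Ribotag RNA of NdpKO retina could come from bipolar cells or from the pulldown. In cells annotated as bipolar the median change of these markers was -0.0026 log2 (quartiles -0.18 and 0.15, 1 of 18 called). The lowest log2 ratio of the share of these cells over all settings was -0.4652 (lowest pair of libraries -0.9983), against a marker median of -1.57, unshifted. These values speak against lower expression in annotated bipolar cells, or fewer such cells, as the whole cause. The annotation may itself rest on such markers, and a cell that lost them could then leave the class. The median within the class therefore cannot decide alone. Lists of 4 cell types did not fall alike, with 1.876 log2 between their highest and lowest medians, which speaks against a general loss of other cells' RNA. The markers stood at 0.7434 log2 in wild-type Ribotag RNA over wild-type whole retina, as extra bipolar RNA in the WT pulldown would give. Protein-coding genes made up 85.6 and 83.3 percent of TPM in the WT Ribotag libraries and 66.1 and 67.4 percent in WT whole retina. Part of that difference may therefore come from scaling. A hypothesis to test is that the WT pulldown also took RNA from bipolar cells, which a repeat with bipolar reporter controls would show.

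The many calls in whole retina may reflect genotype, library batch or sex. Of the calls also measured in sums of all single cells, 62.6 percent had the same sign there, against 55.6 percent of all genes, and genotype and batch cannot be told apart. Of the calls 3.32 percent lay on the X or Y chromosome, which does not bear on autosomal effects of sex. Xist stood at 0.101 and 0.0736 TPM in NdpKO against 7.51 and 18.9 TPM in WT, so sex makeup went with genotype and cannot be told apart from it either. Of 177 genes called in both data sets 168 had the same sign, and a test of the genotype part would need libraries of both genotypes prepared together.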
